A study of Mus musculus with 59 samples.

How the data were processed

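Total RNA from 59 pieces of mouse left ventricle was measured on Affymetrix arrays, 1 piece per array, per the labels. The deposited values were intensities on a linear scale, scaled by the authors so that the mean of the values between the 2nd and 98th percentile was nearly the same on every array (499.2 to 499.9). The tool and the target of that scaling are not given in the sources used here. No value was below 0 and 4 were exactly 0. Groups were taken from the labels, which name the region (sham upper, sham lower, infarct or remote), the time and a number in each title. The labels do not say what the title number stands for. It was taken as the number of the mouse, and it entered the fit as described below.

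Of 12488 probe sets, 66 control probe sets, 396 assigned to several genes and 1193 assigned to none were left out of the gene tests, and 10833 with 1 gene were kept. They covered 8251 genes, of which 2073 had more than 1 probe set and were represented by the one with the highest mean. Gene names were checked against a table of the mouse annotation GRCm38.p6, which changed 0 symbols. Genes were kept when their intensity reached 108.2, the 40th percentile of all values, on at least 3 arrays, which left 6668 genes. Intensities were changed to log2 after 45.6 was added, 0.25 times the median of all values. The signal near background limits the genes that can be followed, since the added value shrinks their changes.

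Differences were tested in R 4.3.3 with limma 3.58.1, in 1 model of 23 groups (region by time) over all 59 arrays. The title number was a random block with a consensus correlation of 0.148. The fit had 36 residual degrees of freedom and 4.44 prior ones. P values of the moderated t and F tests were adjusted by Benjamini-Hochberg within each comparison, and an adjusted p below 0.05 is called passing. The infarct and remote regions were each compared with the sham upper region, which the labels name as the control of both, and with each other, at 6 times. F tests asked for a difference from sham at any time, for an infarct effect that differed between times, and for a difference between times in sham upper tissue. Sham lower and upper tissue were compared with the title number as a fixed block. Gene lists written before the data were examined were tested with camera on the moderated statistics, with a preset correlation of 0.01 and again with the correlation estimated from the data, adjusted over the 666 tests of 37 lists in 18 comparisons. A further list had fewer than 4 measured genes and was left out. Of the 1047 genes in the lists, 772 were measured. For the sham time course the lists were tested with Fisher's exact test. Array quality ratios were compared with exact two-sided permutation tests. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

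The groups, tests, alternatives and the rule for naming genes were set before the data were examined, except that the sham lower array alone as control was added later. Some tests of explanations were also added later, and they are named where the flagged results are given. Genes are named from those that passed and whose 3 arrays of either group lay beyond all 3 of the other. The rule takes the 8 largest rises and 6 largest falls per time for infarct against sham, 5 and 5 for remote against sham, 4 and 4 for infarct against remote, and the 8 smallest adjusted p values for the sham time course and for sham lower against upper. It adds up to 4 members per list at the time with the most calls, and a fixed panel of genes whatever their result. Alternatives were an offset of 0.05 or 1 times the median, quantile normalization, no filter, every probe set tested, no replicate block, a fixed block, only the 2 groups compared, sham upper and lower arrays together as control, an estimated correlation for the lists, beta-actin in place of Gapdh, and each array left out.

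The scripts were tested on simulated data with the design of the study and 50 changed genes of each size among 6668. For infarct against sham at 24 h they recovered 38% of changes of 0.5, 86% of 1, 98% of 2 and 100% of 3 on the log2 scale, with 11 unchanged genes called. A comparison with no change gave 0 calls by limma. The simulation gave each gene the same spread in every group and the same correlation at every time. It thus cannot show how the model fares where real groups differ in spread. A simulated correlation of 0.15 between arrays with the same number was found as 0.158. Across the 59 real arrays the highest correlation between 2 arrays was 0.986, and 0 pairs were identical.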

Results

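Gene expression was measured on Affymetrix oligonucleotide arrays in left ventricle tissue of mice with a myocardial infarction and of sham-operated mice, with 1 array per piece of tissue. Tissue was collected 1 h, 4 h, 24 h, 48 h, 1 week and 8 weeks after surgery. Infarcted mice gave a piece of the infarcted region, between the left anterior descending (LAD) coronary artery and the apex, and a piece of the remote region, which lies above that artery outside the infarct. Sham-operated mice gave a piece of the upper ventricle, which matches the remote region, and in some mice a piece of the lower ventricle, which matches the infarcted region. The infarct, remote and sham upper groups had 3 arrays at each time, 18 arrays per region. The sham lower region had 5 arrays, 1 at each time except 8 weeks, which gave 59 arrays in all. Intensities ran from 0 to 35489 on a linear scale, and the medians of single arrays lay between 157 and 214. Across genes, the lowest correlation between arrays of the same group was 0.923. Single arrays are named here by the rank of the number in their titles among the 3 of their group. From 1 h to 48 h the title numbers of sham and infarcted mice lay in separate ranges, and at 1 week and 8 weeks the ranges overlapped. A difference between sets of mice handled apart would thus be mixed with the effect of infarction in every comparison with sham up to 48 h. Changes are given as log2 ratios ± SE after 45.6 was added to each intensity, and intensities as mean ± SD, with n = 3 arrays in each group compared. The median SE of a change against sham was 0.178. Adjusted p values are those of limma over 6668 genes unless another test is named.

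The infarcted region was set against the sham upper region at each time to find what changed in injured tissue. At 1 h, genes of the immediate early response and of inflammatory signalling were higher in the infarcted region. Fos, a transcription factor gene switched on within minutes of a stimulus, rose by 5.16 ± 0.41 (adjusted p = 9.3e-12). Cxcl1, whose product attracts neutrophils, rose from 287 ± 18 to 5676 ± 608. The stress factor Atf3 rose by 2.82 ± 0.32 and Socs3, a brake on cytokine signalling, by 2.14 ± 0.23 (3.06 on its second probe set). Of 22 measured immediate early genes, 13 rose and 0 fell, 16 rose when adjusted over the list alone, and camera gave an adjusted p = 2.2e-23, with an adjusted p = 2.2e-04 with an estimated correlation. Of 34 cytokine and chemokine genes, 13 rose and 0 fell (14 rose when adjusted over the list alone). Their camera test gave an adjusted p = 5.1e-14, and an adjusted p = 0.0088 with an estimated correlation. Among the falls, Ephx1, an epoxide hydrolase gene, went from 602 ± 109 to 150 ± 5, a call that ended against the single sham lower array of that time. In all, 244 genes were higher and 208 lower, of which 46 and 18 differed at least 2-fold. The arrays of the 2 groups did not overlap for 25.2% of genes, where chance gives 10%. Without the sham array with the lowest title number 206 genes were called, and without each infarct array, in order of title number, 293, 272 and 271. With the sham lower array added to the control 225 genes were called, with the sham lower array alone 23, and with only the 2 groups in the fit 40.

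At 4 h inflammatory, early response and heat shock genes were higher in the infarcted region. Il6, an inflammatory cytokine gene, rose from 33 ± 36 to 3561 ± 241, a log2 change of 5.60 ± 0.38 (adjusted p = 2.5e-14). Hspa1a, an inducible heat shock chaperone gene, rose by 5.04 ± 0.48 and its neighbour Hspa1b by 4.95 ± 0.48. Nppb, the gene of the natriuretic peptide BNP that ventricles make under load, rose by 1.28 ± 0.28 (adjusted p = 0.0017). Immediate early genes rose in 18 of 22 cases and fell in 0 (21 rose when adjusted over the list alone), with a camera adjusted p = 1.7e-45 and an adjusted p = 2.7e-08 with an estimated correlation. Cytokine and chemokine genes rose in 19 of 34 (22 when adjusted over the list alone) and heat shock genes in 8 of 15 (9 when adjusted over the list alone), with 0 falls in either list. Both lists passed with an estimated correlation (adjusted p = 1.9e-06 and 1.2e-04), as did the unfolded protein response (5 of 16 higher, 1 lower; 9 and 1 when adjusted over the list alone; adjusted p = 2.3e-04 with an estimated correlation) and endothelial markers (8 of 21 higher, 0 lower; 8 and 1 when adjusted over the list alone; adjusted p = 0.022 with an estimated correlation). Fntb, which encodes a subunit of protein farnesyltransferase, fell by 1.93 ± 0.27 (fell by 1.48 against the sham lower array alone), and Ucp3, a mitochondrial carrier gene, fell by 1.32 ± 0.34. In all, 349 genes were higher and 446 lower, 106 and 45 of them at least 2-fold, and 37.9% did not overlap (10% by chance). Without the infarct array with the middle title number 523 genes were called, and 142 with the sham lower array alone as the control.

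At 24 h the infarcted region carried transcripts typical of neutrophils and a broad stress response, while many genes of energy metabolism were lower. S100a9 and S100a8, which encode the abundant calcium-binding proteins of neutrophils, rose by 5.32 ± 0.53 and 4.87 ± 0.46 (adjusted p = 9e-11 and 2.7e-11). The chemokine gene Cxcl2 rose from 22 ± 10 to 3684 ± 1095, and Il6 by 5.96 ± 0.38. Hmox1, the heme-degrading enzyme gene, rose by 3.36 ± 0.20. Nppb stood at 19124 ± 1313 against 5720 ± 1377 in sham. Cytokine and chemokine genes rose in 29 of 34 and fell in 1, the same counts when adjusted over the list alone, with a camera adjusted p = 3.6e-25 and an adjusted p = 1.2e-04 with an estimated correlation. The unfolded protein response (14 of 16 higher, 1 lower; 15 and 1 when adjusted over the list alone) and neutrophil markers (10 of 14 higher, 0 lower, the same when adjusted over the list alone) passed with an estimated correlation at adjusted p = 7.8e-05 and 9.1e-04. Oxidative phosphorylation genes fell in 40 of 61 with 0 rises (43 falls when adjusted over the list alone), with a camera adjusted p = 3.1e-05 that was lost, adjusted p = 0.73 with an estimated correlation. Macrophage markers rose in 19 of 28 and fell in 2, also when adjusted over the list alone (camera adjusted p = 6.7e-05; adjusted p = 0.56 with an estimated correlation). Ptp4a3, a phosphatase gene, fell by 2.35 ± 0.24 (adjusted p = 2.1e-04 for a smaller fall against the sham lower array alone) and Inmt, a methyltransferase gene, fell by 2.80 ± 0.28. In all, 1240 genes were higher and 1598 lower, 438 and 300 of them at least 2-fold, and 46.8% did not overlap (10% by chance). Against the sham lower array alone 1630 genes were called, 1490 of them also called against the sham upper arrays.

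At 48 h many neutrophil, macrophage and cell division genes were higher, and most genes of mitochondrial energy supply were lower. Arg1, an arginase gene of alternatively activated macrophages, rose by 6.04 ± 0.61 (adjusted p = 9.8e-11), and Chil3, another macrophage gene, by 5.96 ± 0.42. Mmp9, a matrix-degrading protease gene, rose from 22 ± 7 to 1743 ± 22. The matrix gene Tnc, which encodes tenascin C, rose by 3.94 ± 0.36 (2.55 on its second probe set). Neutrophil markers rose in 9 of 14 and fell in 0, also when adjusted over the list alone, with a camera adjusted p = 3.4e-07 and an adjusted p = 0.0026 with an estimated correlation. Macrophage markers rose in 23 of 28 and fell in 0, also when adjusted over the list alone (camera adjusted p = 2.4e-09; adjusted p = 0.28 with an estimated correlation). Cell cycle genes rose in 24 of 40 and fell in 1, also when adjusted over the list alone (camera adjusted p = 5.6e-04; adjusted p = 0.56 with an estimated correlation). Oxidative phosphorylation genes fell in 55 of 61 and fatty acid oxidation genes in 28 of 31, with 0 and 2 rises and the same counts when adjusted over the list alone. Their camera adjusted p values of 6.7e-18 and 8.8e-09 were lost, adjusted p = 0.28 and 0.33 with an estimated correlation. Art1, an ADP-ribosyltransferase gene of striated muscle, fell by 2.96 ± 0.20. Atp2a2, which encodes the calcium pump of the sarcoplasmic reticulum, fell from 17089 ± 1971 to 7990 ± 2242 (adjusted p = 3.4e-04). In all, 1666 genes were higher and 1725 lower, 10.1% and 7.59% of the tested genes changed at least 2-fold in each direction, and 58.5% did not overlap (10% by chance).

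At 1 week transcripts of matrix, macrophages and cell division were high in the infarcted region, and those of contraction and energy supply were low. Postn, the periostin gene of activated fibroblasts, rose from 525 ± 114 to 11913 ± 978, a log2 change of 4.41 ± 0.28 (adjusted p = 2.1e-16), and Col1a1, a fibrillar collagen gene, rose from 1782 ± 716 to 14786 ± 836, a log2 change of 3.09 that was 1.68 on its second probe set. The macrophage gene Lgals3 rose by 5.59 ± 0.49 and the mitotic kinase gene Cdk1 by 3.21 ± 0.38. Myh6, the main myosin heavy chain gene of the adult mouse heart, went from 26608 ± 1394 to 5703 ± 4453. The infarct array with the highest title number stood apart, with Myh6 at 580 against 8651 and 7877, and with 1571 of the fat cell gene Adipoq and 5604 of the immunoglobulin gene Igkv6-23, genes chosen after their values were seen. Adipoq on the other infarct arrays, at 390 and 281, also lay above the highest sham upper value of 114. Without the infarct array with the highest title number the fall of Myh6 was smaller but passed, and 3720 genes were called. Hrc, a calcium-binding protein gene of the sarcoplasmic reticulum, fell by 4.14 ± 0.22. Collagen and matrix genes rose in 31 of 36 and fell in 2, macrophage markers rose in 27 of 28 and fell in 0, and cell cycle genes rose in 34 of 40 and fell in 0, the same counts when adjusted over the list alone. Their camera adjusted p values were 4e-16, 2.4e-13 and 1.1e-07, and all were lost, adjusted p = 0.072, 0.15 and 0.27 with an estimated correlation. Genes of the citric acid cycle fell in 19 of 22 with 0 rises, also when adjusted over the list alone, with a camera adjusted p = 2.9e-19 and an adjusted p = 0.043 with an estimated correlation. Oxidative phosphorylation genes fell in 55 of 61 with 0 rises (camera adjusted p = 2e-38; adjusted p = 0.051 with an estimated correlation) and sarcomere genes in 18 of 26 with 2 rises (camera adjusted p = 1e-04; adjusted p = 0.51 with an estimated correlation), the same counts when adjusted over the list alone. In all, 2316 genes were higher and 1714 lower, 1074 and 763 of them at least 2-fold, and 69.0% did not overlap (10% by chance). Quantile normalization moved the median of all genes by -0.17 on the log2 scale, and the share of higher genes among those called went from 57.5% to 47.4%.

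At 8 weeks matrix genes were higher, and metabolic genes lower, than in sham tissue. Postn was at 5485 ± 2126 against 679 ± 73 in sham, a log2 change of 2.85 ± 0.28 (adjusted p = 4.8e-09), and Mmp12, a macrophage elastase gene, was higher by 3.47 ± 0.60 (2.24 on its second probe set). Nppa, the atrial natriuretic peptide gene that stressed ventricles switch on, was higher by 2.22 ± 0.31, and Eci1, a fatty acid oxidation gene, was lower by -1.34 ± 0.22. The calls of Nppa and Eci1 ended with only the 2 groups in the fit, while those of Postn and Mmp12 held. Collagen and matrix genes were higher in 27 of 36 and lower in 1 (29 and 1 when adjusted over the list alone), with a camera adjusted p = 5.7e-21 and an adjusted p = 0.028 with an estimated correlation. Fibroblast markers were higher in 12 of 23 and lower in 1 (14 and 1 when adjusted over the list alone), with an adjusted p = 0.029 with an estimated correlation. Oxidative phosphorylation genes were lower in 40 of 61 and higher in 0 (47 lower when adjusted over the list alone), with a camera adjusted p = 3.8e-16 that was lost, adjusted p = 0.33 with an estimated correlation. In all, 763 genes were higher and 644 lower, 207 and 37 of them at least 2-fold, and 34.3% did not overlap (10% by chance). Quantile normalization took the share of higher genes among those called from 54.2% to 49.4%. Without the sham array with the highest title number 896 genes were called, and 623 without the infarct array with the highest title number. That infarct array carried 3442 of Adipoq and 2904 of Car3, genes of fat cells, where the highest sham upper values were 114 and 121. The infarct array with the middle number was also above these, at 835.5 and 864.5. The array with the highest number had the lowest Acadm of the 3, a fatty acid oxidation gene, at 4784 against 13084 and 9338. These 3 genes were chosen after their values were seen. The fit of the 2 groups alone called 11 genes.

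The remote region was set against the sham upper region, which comes from the same part of the ventricle, to find what changed in tissue outside the infarct. At 1 h the remote region showed early response and inflammatory genes too. Fos rose by 4.98 ± 0.41 (adjusted p = 2.9e-11), Cxcl1 from 287 ± 18 to 3709 ± 474, and Il6 by 2.30 ± 0.38. Junb, another immediate early transcription factor gene, rose by 1.47 ± 0.24 (2.73 on its second probe set). Immediate early genes rose in 13 of 22 and fell in 0 (17 rose when adjusted over the list alone), with a camera adjusted p = 2.6e-17 and an adjusted p = 0.0024 with an estimated correlation. Cytokine and chemokine genes rose in 10 of 34 and fell in 0 (12 rose when adjusted over the list alone), with a camera adjusted p = 1.9e-08 that was lost, adjusted p = 0.073 with an estimated correlation. Prep, a peptidase gene, fell by 1.64 ± 0.32, a call that ended with only the 2 groups in the fit. In all, 369 genes were higher and 167 lower, 34 and 13 of them at least 2-fold, and 32.4% did not overlap (10% by chance). Without the sham arrays with the lowest and middle title numbers 289 and 265 genes were called, and without the remote arrays with the lowest and middle numbers 184 and 356. The fit of the 2 groups alone called 100 genes.

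At 4 h 116 genes passed in the remote region, among them stress and inflammatory genes that rose. Il6 went from 33 ± 36 to 1329 ± 294, a log2 change of 4.19 ± 0.38 (adjusted p = 4.1e-10), Atf3 rose by 3.51 ± 0.32, Hspa1a by 3.42 ± 0.48 and S100a8 by 2.48 ± 0.46. Cytokine and chemokine genes rose in 17 of 34 and fell in 0 (21 rose when adjusted over the list alone), with a camera adjusted p = 5.5e-43 and an adjusted p = 6.4e-08 with an estimated correlation. Immediate early genes (12 of 22 higher, 0 lower; 16 and 1 when adjusted over the list alone), heat shock genes (4 of 15 higher, 0 lower; 7 and 0 when adjusted over the list alone) and neutrophil markers (3 of 14 higher, 0 lower; 5 and 0 when adjusted over the list alone) also passed with an estimated correlation, at adjusted p = 1.9e-06, 0.0038 and 0.0026. In all, 95 genes were higher and 21 lower. Of the higher genes 61 rose at least 2-fold, and 0 of the lower genes fell that far by limma, with 828 genes at an unadjusted p below 0.05 in either direction. The groups did not overlap for 24.0% of genes (10% by chance). Without each sham array, in order of title number, 75, 71 and 74 genes were called, and 59 without the remote array with the lowest number. That remote array carried 2792 of S100a8, against 957 and 1235 on the others. It also carried 2658 of the fat cell gene Adipoq, against 87.1 and 82, a gene chosen after its values were seen. The atrial gene Myl7, chosen in the same way, was raised on all 3 remote arrays, at 267.7, 637.9 and 527.6. The highest sham upper value at 4 h was 95.

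At 24 h genes that respond to glucocorticoids, metals and oxidative stress were higher in the remote region, together with natriuretic peptide. Lcn2, which encodes the acute phase protein lipocalin 2, rose from 825 ± 240 to 4066 ± 912 (log2 change 2.26 ± 0.30, adjusted p = 1.8e-06), while a second, dimmer probe set of Lcn2 gave 0.01 (adjusted p = 0.99). Gadd45g, a growth arrest gene, rose by 2.53 ± 0.28, the metallothionein gene Mt2 by 1.77 ± 0.24, and Nppb from 5720 ± 1377 to 18680 ± 3898. Glucocorticoid response genes rose in 9 of 20 and fell in 0, also when adjusted over the list alone, with a camera adjusted p = 2.4e-12 and an adjusted p = 0.0022 with an estimated correlation. Oxidative stress and metal response genes (6 of 19 higher, 0 lower; 6 and 1 when adjusted over the list alone) and fetal and hypertrophy genes (8 of 19 higher, 0 lower; 10 and 0 when adjusted over the list alone) passed with an estimated correlation as well, at adjusted p = 0.0011 and 0.011. In sham upper tissue 14 of 20 glucocorticoid and 11 of 19 oxidative stress and metal genes differed between times, against 18.7% of all genes. The sham level of these 2 lists was thus itself not steady. Inmt fell by 1.75 ± 0.28. In all, 194 genes were higher and 105 lower, 72 and 12 of them at least 2-fold, and 23.4% did not overlap (10% by chance). Without the sham array and without the remote array with the middle title number, 184 and 130 genes were called, and 51 with only the 2 groups in the fit. The remote array with the highest number, which has no infarct partner, stood apart. It carried 2401.9 of S100a8, against 243.8 and 672.8, and 917.9 of Arg1, against 14.3 and 72.6. Both genes were picked for this after their values were seen. Without that array 408 genes were called.

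At 48 h genes that respond to metals and oxidative stress and fetal and hypertrophy genes were higher in the remote region. Mt2 was higher by 2.33 ± 0.24 (adjusted p = 3.1e-09), at 12004 ± 1232 against a mean of 2379 in sham. Serpina3n, an acute phase protease inhibitor gene, was higher by 2.67 ± 0.22, at 7932 ± 1036, and Nppb by 1.69 ± 0.28. Lcn2 was higher by 3.18 ± 0.30, but its second probe set gave 0.24 (adjusted p = 0.55). Dbp, a transcription factor gene driven by the circadian clock, fell by 2.54 ± 0.33, and H2-Aa, an antigen presentation gene of MHC class II, fell by 1.95 ± 0.37. Fetal and hypertrophy genes were higher in 8 of 19 and lower in 0 (9 higher when adjusted over the list alone), with a camera adjusted p = 3.8e-09 and an adjusted p = 0.018 with an estimated correlation. Oxidative stress and metal response genes were higher in 7 of 19 and lower in 1 (8 and 2 when adjusted over the list alone), with a camera adjusted p = 4.8e-06 and an adjusted p = 0.008 with an estimated correlation. Glucocorticoid response genes were higher in 7 of 20 and lower in 1 (8 and 1 when adjusted over the list alone), with an adjusted p = 0.029 with an estimated correlation. As at 24 h, the sham level of this list and of the oxidative stress and metal list was not steady between times. Collagen and matrix genes were higher in 11 of 36 and lower in 1 (13 and 1 when adjusted over the list alone), with a camera adjusted p = 6.1e-06 that was lost, adjusted p = 0.45 with an estimated correlation. In all, 296 genes were higher and 292 lower, 67 and 35 of them at least 2-fold, and 24.7% did not overlap (10% by chance). Without the sham array with the middle title number 333 genes were called, without the remote array with the highest number 287, and with only the 2 groups in the fit 85.

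At 1 week the remote region differed from sham tissue at more genes than at any other time in these comparisons of remote tissue. Matrix genes rose there as well, and Postn went from 525 ± 114 to 12477 ± 1009, a log2 change of 4.47 ± 0.28 (adjusted p = 2.1e-15), and Col1a1 reached 18782 ± 1150, a log2 change of 3.43 that was 1.26 on its second probe set. Nppa rose from 924 ± 163 to 5954 ± 1096. The macrophage gene Lgals3 rose by 4.03 ± 0.49. The fat cell gene Adipoq was at 268.5, 161.9 and 1178 on the 3 remote arrays, above the highest sham upper value of 114. The remote array with the highest title number also carried 3576 of the immunoglobulin gene Igkv6-23. Adipoq and Igkv6-23 were chosen after their values were seen. Slc2a4, which encodes the insulin-responsive glucose transporter GLUT4, fell by 1.32 ± 0.26. The myosin gene Myh6 did not pass at -0.49 ± 0.41 (adjusted p = 0.37). Its 3 remote values, 16398 to 22083, still all lay below the 3 sham values, 25102 to 27851. The SE pools all groups, among them the infarct array at 580 named above. Collagen and matrix genes rose in 32 of 36 and fell in 0, also when adjusted over the list alone, with a camera adjusted p = 1.4e-38 and an adjusted p = 9.1e-04 with an estimated correlation. Matrix proteases and their inhibitors rose in 12 of 18 and fell in 0 (14 rose when adjusted over the list alone), with an adjusted p = 0.03 with an estimated correlation. Macrophage markers rose in 27 of 28 and fell in 0, also when adjusted over the list alone (camera adjusted p = 4.6e-17; adjusted p = 0.079 with an estimated correlation). Oxidative phosphorylation genes fell in 54 of 61 with 0 rises, also when adjusted over the list alone (camera adjusted p = 8.2e-19; adjusted p = 0.27 with an estimated correlation). In all, 1375 genes were higher and 1178 lower, 491 and 162 of them at least 2-fold, and 48.0% did not overlap (10% by chance). Quantile normalization moved the median of all genes by -0.11 on the log2 scale, and the share of higher genes among those called went from 53.9% to 44.9%.

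At 8 weeks 8 genes were higher in the remote region than in sham tissue and 0 were lower by limma, with 545 genes at an unadjusted p below 0.05 in either direction. Postn was at 3162 ± 1570 against 679 ± 73, a log2 change of 2.05 ± 0.28 (adjusted p = 3.4e-05), and Mfap5, a gene of elastic microfibrils, was higher by 1.30 ± 0.21, while its second probe set gave 0.29 (adjusted p = 0.78). Both calls ended with only the 2 groups in the fit. Genes of collagen and matrix were higher in 3 of 36 and lower in 0 (11 higher when adjusted over the list alone), with a camera adjusted p = 1.2e-16 that was lost, adjusted p = 0.063 with an estimated correlation. Fibroblast markers were higher in 2 of 23 and lower in 0 (7 higher when adjusted over the list alone), with a camera adjusted p = 3.5e-09 and an adjusted p = 0.034 with an estimated correlation. The groups did not overlap for 18.6% of genes (10% by chance). The count was 3 under quantile normalization, 2 with no filter, 2 with no replicate block and 0 with only the 2 groups in the fit. Without each of the sham arrays with the middle and highest title numbers it was 2, and without the remote arrays with the lowest and highest numbers 4 and 2.

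**Figure D1:**
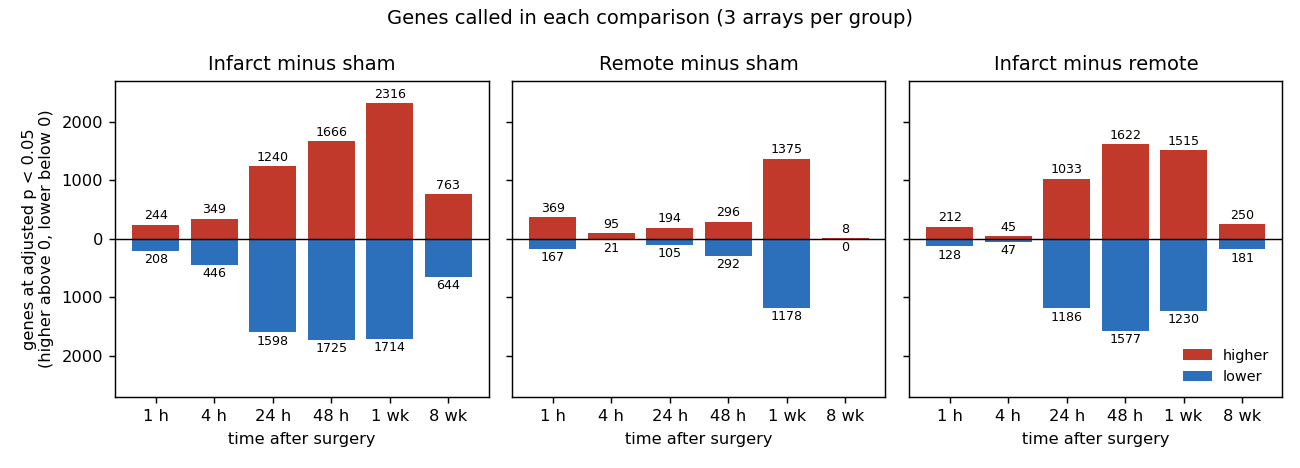
Number of genes with an adjusted p below 0.05 (vertical axis, higher above 0 and lower below 0) at each time after surgery (horizontal axis) for infarct minus sham, remote minus sham and infarct minus remote, with 3 arrays per group. The most genes were called in the infarct at 1 week, 2316 higher and 1714 lower, and the fewest in the remote region at 8 weeks, 8 higher and 0 lower.

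The infarcted and remote regions were compared directly, since a gene past the threshold against sham in 1 region and not in the other is not thereby shown to differ between them. At 1 h early response genes mostly did not pass between the regions: Fos differed by 0.18 ± 0.38 (adjusted p = 0.86) and Il6 by 0.69 ± 0.35 (adjusted p = 0.27). Of the immediate early genes 1 of 22 was higher in the infarct, and 0 of 34 cytokine and chemokine genes passed by limma, also when adjusted over the list alone. Ephx1 was lower in the infarct by -1.53 ± 0.30 (adjusted p = 0.0034). Lama1, a laminin gene of basement membranes, was higher by 1.38 ± 0.24, a call that ended with only the 2 groups in the fit. In all, 212 genes were higher and 128 lower in the infarct, 24 and 16 of them at least 2-fold, and 29.2% did not overlap (10% by chance). Quantile normalization took the share of higher genes among those called from 62.4% to 51.2%. Without the infarct arrays with the lowest and highest title numbers 53 and 150 genes were called, and without each remote array, in order of title number, 87, 182 and 144. With no replicate block 172 genes were called, with a fixed block 171, and with the 2 groups alone in the fit 8.

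At 4 h some stress genes were higher in the infarct than in the remote region. Hspa1b was higher in the infarct by 2.01 ± 0.44 (adjusted p = 0.011), at 6486 ± 1157 against 1565 ± 185, and the early response gene Egr1 was higher by 1.18 ± 0.27. Fntb was lower by -1.24 ± 0.25. Each of these 3 calls ended when single arrays were left out. For Hspa1b the adjusted p was 0.078 without the middle infarct array, and 0.078 and 0.059 without the middle and highest remote arrays. For Egr1 it was 0.081 and 0.078 without the lowest and middle infarct arrays, and 0.13 and 0.070 without the middle and highest remote arrays. For Fntb it was 0.070 without the highest remote array. Immediate early genes were higher in 6 of 22 and lower in 0 (14 higher when adjusted over the list alone), with a camera adjusted p = 1.6e-17 and an adjusted p = 0.0022 with an estimated correlation. Heat shock genes were higher in 3 of 15 and lower in 0 (4 higher when adjusted over the list alone), with an adjusted p = 0.017 with an estimated correlation. Cytokine and chemokine genes were higher in 5 of 34 and lower in 0 (8 higher when adjusted over the list alone), with a camera adjusted p = 5.9e-05 that was lost, adjusted p = 0.26 with an estimated correlation. In all, 45 genes were higher and 47 lower, 12 and 9 of them at least 2-fold, and 23.9% did not overlap (10% by chance). Without each infarct array, in order of title number, 39, 40 and 45 genes were called, and without the remote arrays with the middle and highest numbers 31 and 24. With no replicate block 50 genes were called.

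At 24 h the acute inflammatory and stress response was higher in the infarct than in the remote region. Il6 was higher by 4.45 ± 0.36 (adjusted p = 2.2e-12), at 3285 ± 890 against 154 ± 141, Hspa1b by 4.11 ± 0.45, and Selp, the P-selectin gene of activated endothelium and platelets, by 3.68 ± 0.24. S100a9 was higher by 2.92 ± 0.50. The natriuretic peptide gene Nppb, raised in both regions against sham, did not pass between them at 0.04 ± 0.27 (adjusted p = 0.93). Unfolded protein response genes were higher in 14 of 16 and lower in 1, also when adjusted over the list alone, with a camera adjusted p = 1.8e-07 and an adjusted p = 6e-05 with an estimated correlation. Cytokine and chemokine genes (26 of 34 higher, 1 lower, the same when adjusted over the list alone) and neutrophil markers (9 of 14 higher, 0 lower; 11 and 0 when adjusted over the list alone) passed with an estimated correlation at adjusted p = 8.1e-04 and 0.001. Rgs5, a gene of pericytes, was lower by -1.69 ± 0.16 and Ptp4a3 by -1.79 ± 0.23. In all, 1033 genes were higher and 1186 lower, 246 and 100 of them at least 2-fold, and 38.6% did not overlap (10% by chance). With only the 2 groups in the fit, 1018 genes were called.

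At 48 h inflammatory cell transcripts were higher, and mitochondrial transcripts lower, in the infarct than in the remote region. Arg1 was higher by 4.68 ± 0.56 (adjusted p = 9e-09), at 6592 ± 998 against 236 ± 139, Mmp9 by 3.99 ± 0.43 and Itgam, an integrin gene of myeloid cells, by 3.32 ± 0.37. Dmpk, a muscle protein kinase gene, was lower by -2.24 ± 0.20 and Art1 by -2.28 ± 0.19. Neutrophil markers were higher in 9 of 14 and lower in 0, also when adjusted over the list alone, with a camera adjusted p = 7.9e-07 and an adjusted p = 0.0038 with an estimated correlation. Macrophage markers were higher in 23 of 28 and lower in 0 (23 and 1 when adjusted over the list alone), and oxidative phosphorylation genes lower in 57 of 61 and higher in 0, also when adjusted over the list alone. Their camera adjusted p values of 1.1e-10 and 4.2e-19 were lost, adjusted p = 0.23 and 0.26 with an estimated correlation. In all, 1622 genes were higher and 1577 lower, 479 and 294 of them at least 2-fold, and 49.0% did not overlap (10% by chance). Quantile normalization took the share of higher genes among those called from 50.7% to 46.8%.

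At 1 week muscle and energy genes were lower, and macrophage genes higher, in the infarct than in the remote region, and matrix genes did not move as one. Tnc was higher by 1.17 ± 0.33 (adjusted p = 0.0038), while Postn did not pass at -0.07 ± 0.26 (adjusted p = 0.86). Neither did Col1a1 at -0.34 ± 0.34 (adjusted p = 0.44), whose second probe set gave 0.42 (adjusted p = 0.058), or Col3a1 at -0.21 (adjusted p = 0.61), for which the lowest adjusted p of its 2 other probe sets was 0.0067, with changes of 0.80 and 0.91. Sgca, a gene of the muscle membrane complex, was lower in the infarct by -2.94 ± 0.24 (adjusted p = 3.3e-12), at a mean of 251 against 2023, and the troponin I gene Tnni3 was lower by -2.55 ± 0.33. Arg1 was higher by 2.88 ± 0.56. Oxidative phosphorylation genes were lower in 52 of 61 and higher in 0 (54 lower when adjusted over the list alone), with a camera adjusted p = 5.5e-43 and an adjusted p = 0.034 with an estimated correlation. Calcium handling and conduction genes were lower in 20 of 29 and higher in 0 (21 lower when adjusted over the list alone), with an adjusted p = 0.034 with an estimated correlation. Macrophage markers were higher in 20 of 28 and lower in 0 (22 higher when adjusted over the list alone), with a camera adjusted p = 8.6e-06 that was lost, adjusted p = 0.49 with an estimated correlation. Genes of collagen and matrix were higher in 13 of 36 and lower in 2, also when adjusted over the list alone (camera adjusted p = 0.16; adjusted p = 0.92 with an estimated correlation). Sarcomere genes were lower in 21 of 26 and higher in 1, also when adjusted over the list alone (camera adjusted p = 2.3e-11; adjusted p = 0.14 with an estimated correlation). Fetal and hypertrophy genes were lower in 10 of 19 and higher in 2, also when adjusted over the list alone (camera adjusted p = 0.0037; adjusted p = 0.35 with an estimated correlation). In all, 1515 genes were higher and 1230 lower, 4.57% and 4.98% of the tested genes differed at least 2-fold in each direction, and 47.0% did not overlap (10% by chance). Quantile normalization took the share of higher genes among those called from 55.2% to 49.1%. With only the 2 groups in the fit, 1810 genes were called.

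At 8 weeks some matrix genes were higher and some metabolic genes lower in the infarct than in the remote region. Sfrp1, which encodes a secreted Wnt inhibitor, was higher by 1.33 ± 0.20 (adjusted p = 2.6e-04), and Dmpk was lower by -1.30 ± 0.20, at 2382 ± 560 against 5834 ± 582. Both calls ended with only the 2 groups in the fit. Genes of collagen and matrix were higher in 15 of 36 and lower in 0 (19 higher when adjusted over the list alone), with a camera adjusted p = 1.3e-11 that was lost, adjusted p = 0.17 with an estimated correlation. Oxidative phosphorylation genes were lower in 13 of 61 and higher in 0 (34 lower when adjusted over the list alone), with a camera adjusted p = 1e-15 that was lost, adjusted p = 0.33 with an estimated correlation. In all, 250 genes were higher and 181 lower, 37 and 4 of them at least 2-fold, and 17.8% did not overlap (10% by chance). Without the infarct arrays with the lowest and highest title numbers 1150 and 7 genes were called. The second of these is the array with the highest Adipoq and Car3 and the lowest Acadm named above. Without each remote array, in order of title number, 249, 36 and 225 genes were called, and 195 with no replicate block. With only the 2 groups in the fit, limma called 0 genes, where the full model had 1568 at an unadjusted p below 0.05.

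**Figure D2:**
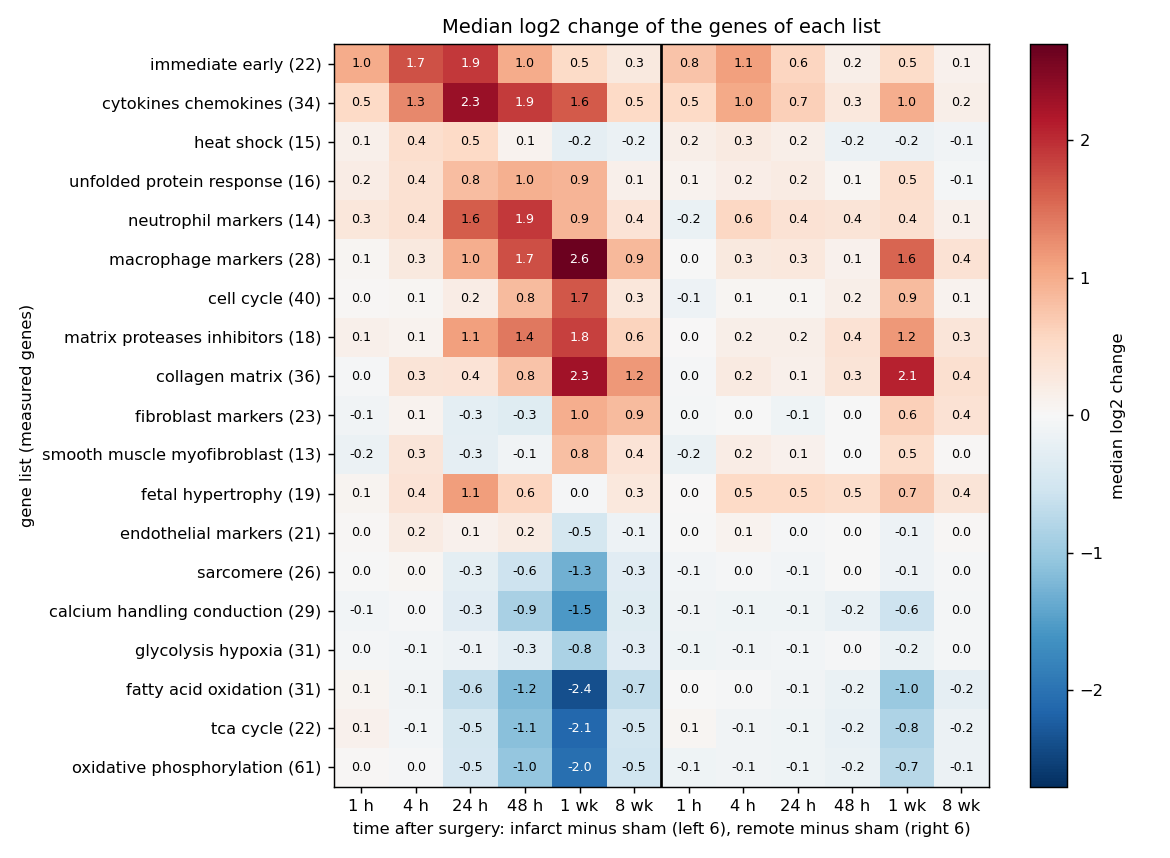
Median log2 change (colour and printed value) of the measured genes of 19 lists (vertical axis, number measured in parentheses) at each time after surgery (horizontal axis), infarct minus sham on the left and remote minus sham on the right. Collagen and matrix genes had medians of 2.27 in the infarct and 2.07 in the remote region at 1 week, where the oxidative phosphorylation medians were -2.03 and -0.74.

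Over all times together, limma's F test asked whether a gene differed from sham at any time. It called 5177 genes (77.6%) for the infarct and 2810 (42.1%) for the remote region. Postn had an adjusted p = 7.2e-18 for the infarct and 1.1e-14 for the remote region, Hmox1 had 1.2e-20 and 1.5e-12, and Myh6 had 3.2e-06 and 0.91. The spread behind both Myh6 values includes the infarct array at 580 at 1 week. A test of whether the infarct effect differed between the times called 4308 genes (64.6%), among them Hmox1 (adjusted p = 3.7e-14), Tnc (2.2e-12) and Myc (2e-11). Myh7, the myosin gene of the fetal ventricle, did not pass in any of these 3 tests (adjusted p = 0.13, 0.44 and 0.18).

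**Figure D3:**
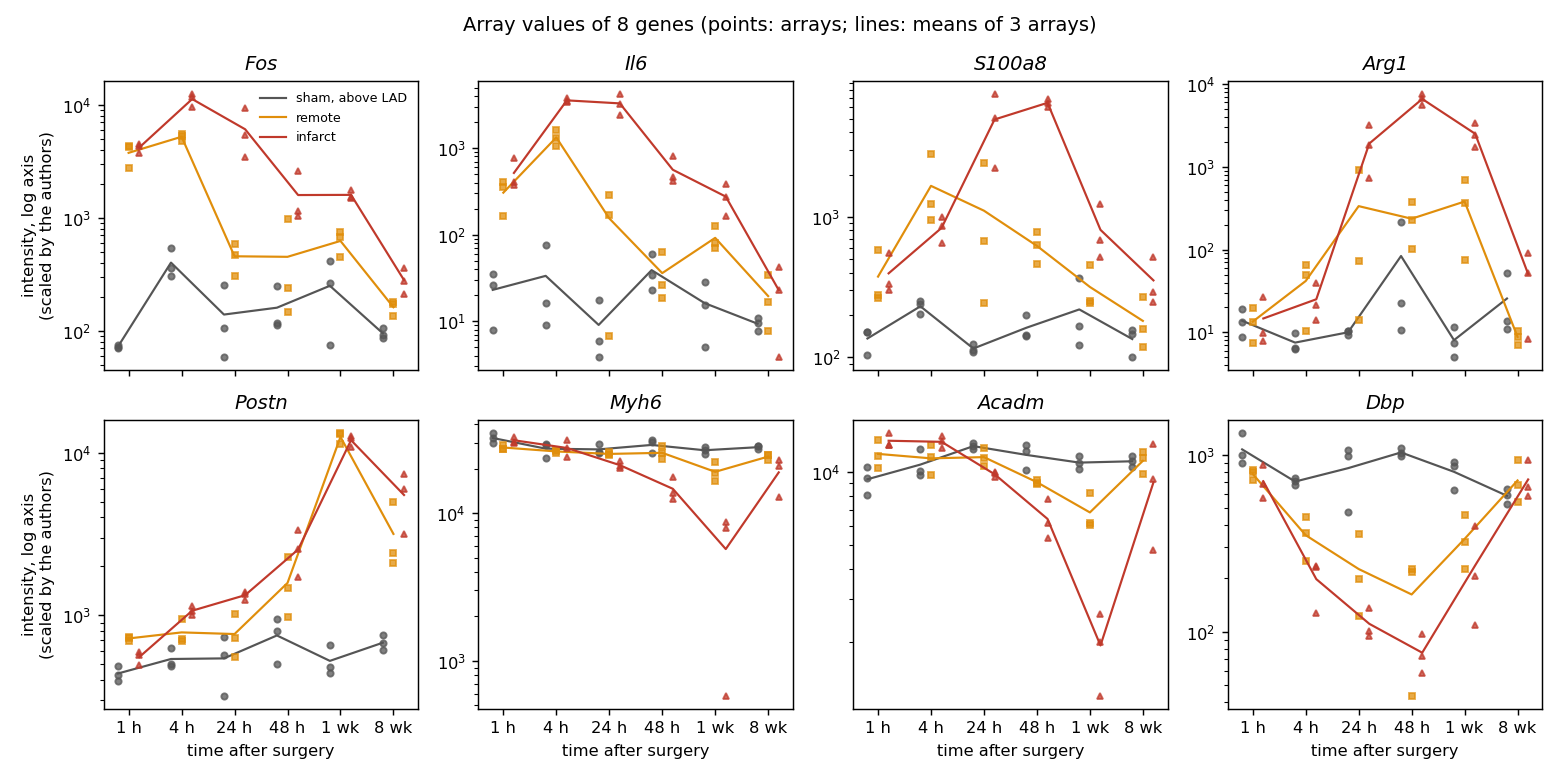
Intensity of 8 genes on single arrays (points, log axis) and the means of 3 arrays (lines) at each time after surgery (horizontal axis) in sham upper, remote and infarcted tissue. Fos rose in both regions of infarcted mice at 1 h, Arg1 reached 6592 in the infarct at 48 h, and Postn reached 11913 in the infarct and 12477 in the remote region at 1 week.

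The sham upper region was compared with itself over the 6 times to find how far control tissue differed between collections. In these 18 arrays 1244 genes (18.7%) differed between times. Cebpd, a transcription factor gene of the acute phase and glucocorticoid response, had its highest level at 4 h, 5271 ± 434, and its lowest at 24 h, 1323 ± 217 (adjusted p = 1.5e-04). Igtp, an interferon-induced GTPase gene, stood at 1118 ± 87.7 at 8 weeks and at 280 ± 164 or less at the other times (adjusted p = 5.1e-04). Glucocorticoid response genes differed in 14 of 20 (15 when adjusted over the list alone), more often than other genes by Fisher's exact test (adjusted p = 2.7e-05), and so did oxidative stress and metal response genes, in 11 of 19 (11 when adjusted over the list alone; Fisher's exact test, adjusted p = 0.0029). Without the sham array with the middle title number at 1 h 763 genes were called, and without those with the middle and highest numbers at 1 week 715 and 766.

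The 5 arrays of sham lower ventricle were compared with the 5 sham upper arrays of the same times and title numbers to find how far position alone changed expression. By limma 0 genes passed, with 962 at an unadjusted p below 0.05 where chance gives 5% of genes, and the lowest adjusted p was 0.171. Fntb and Ptp4a3 were among the 8 genes with the smallest p, lower in the lower ventricle by -1.09 and -0.72, and Dmpk was lower by -0.73. The infarct lies in the lower ventricle. A true difference of position would thus be mixed into the falls of these genes in the infarct against sham upper or remote tissue. An offset of 1 times the median intensity, in place of 0.25 times, gave 7 genes.

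The ratio of 3-prime to 5-prime signal of control transcripts was compared between infarct and sham arrays as a measure of RNA integrity. The Gapdh ratio lay between 0.756 and 0.953 and the beta-actin ratio between 1.16 and 1.76 on the 59 arrays. The difference in Gapdh ratio was largest at 48 h, 0.823 ± 0.012 in the infarct against 0.899 ± 0.049 in sham (exact two-sided permutation p = 0.1). The difference in beta-actin ratio was largest at 1 week, 1.21 ± 0.0455 against 1.46 ± 0.260 (exact two-sided permutation p = 0.1), and at 1 h it was 0.0687 (exact two-sided permutation p = 0.1). No time gave an exact permutation p below 0.1 for Gapdh or beta-actin, and 0.1 is the smallest that 3 against 3 arrays can give.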

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

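In this part the test of position in the ventricle, the tests of carried-over tissue and of an unusual remote array, and the test of a wholly local change of Dbp and Tef were chosen only after the result was seen. The first item is a tested difference between times: the infarct effect differed between the 6 times for 64.6% of genes. The others are tested differences between the regions, since the infarct and remote effects against the same sham arrays differed for 5.10% of genes at 1 h, 1.38% at 4 h, 33.3% at 24 h, 48.0% at 48 h, 41.2% at 1 week and 6.46% at 8 weeks.

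The arrays were also split in other ways. For the tests over all times, 1 of 100 splits, the real one, gave as many genes, the smallest share that 100 splits can give. In the comparisons with sham, such splits cannot part infarction from sets of mice handled apart. The real and highest other counts were 5177 and 4304 for the infarct at any time, 2810 and 1961 for the remote region, 4308 and 2573 for the infarct effect by time, and 1244 and 92 for the sham time course. Some of these splits kept the real groups at some of the times. For 3 arrays against 3 there are only 10 splits, too few for a share under 0.05, and 1 of 10, the real one, gave as many genes in each comparison. From 1 h to 8 weeks the real and highest other counts were 452 and 5, 795 and 0, 2838 and 214, 3391 and 23, 4030 and 0, and 1407 and 110 for infarct against sham. They were 536 and 5, 116 and 1, 299 and 8, 588 and 5, 2553 and 3, and 8 and 4 for remote against sham. For infarct against remote they were 92 and 0 at 4 h, 2219 and 409 at 24 h, 3199 and 127 at 48 h, and 2745 and 566 at 1 week. At 1 h the real share of genes was 5.10% and the highest other count was 2, and at 8 weeks the shares were 6.46% and 5.32%. Read as pairs by title number, the real split parts all pairs, and 4 of the 10 splits do so at each time but 24 h. At 24 h only 2 numbers have a partner. Among the splits that part all pairs the highest other counts were 2 at 1 h, 0 at 4 h, 119 at 48 h, 1 at 1 week and 35 at 8 weeks. The other splits put both arrays of some pairs in the same group.

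The first pattern was the set of genes called between infarct and remote tissue at 1 h. A shift of dim probe sets was argued against, since 52.1% of the called genes lay below the median intensity of the tested genes. Early response genes did not make up this set either: 1 of 56 was called, an odds ratio of 0.336 (Fisher's exact test, one-sided p = 0.947). Among all genes 5.10% were called. The test asks only for a surplus of early response genes, so regional differences of these genes below the threshold stay open. A difference between lower and upper ventricle that sham hearts also have stays open, and 82.1% of the called genes had the same sign in sham lower minus upper tissue, against 58.2% of all genes. The shift went the same way in 5 of 5 pairs (exact one-sided p = 0.0312, the smallest that 5 pairs can give). This was not particular to 1 h: from 4 h to 8 weeks the genes called between the regions also shifted the same way in 5 of 5 pairs, and 68.5%, 65.2%, 66.7%, 70.5% and 84.0% of them had the same sign, against 58.3% to 62.8% of all genes. Position in the ventricle is thus a candidate explanation for part of this set.

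The second pattern was the remote region at 1 week, which lay far from sham, toward the infarct. If carried-over tissue with the make-up of the infarct piece were the whole cause, every gene would imply the same share of it. The shares were taken for list genes that passed for infarct against sham at 1 week. The implied share had a median of 78.1% for 33 collagen genes and 54.4% for 130 muscle genes, 23.7 points apart (permutation p = 1e-05, the smallest that 100000 resamples can give), with quartiles of 46.5% to 99.8% and 45.2% to 64.0%, which overlap. For 27 macrophage genes it was 39.3% (permutation p = 3e-05 against collagen). Both permutations exchanged genes between lists as if they were independent, so these p values do not measure the spread between mice. Each share rests on 1 probe set per gene and was not recomputed on other probe sets. For Col1a1 the chosen set changed by 3.09 in the infarct and 3.43 in the remote region, but the second by 1.68 and 1.26. For Col3a1 the chosen set gave 3.14 and 3.36, but the 2 others spanned 3.43 to 5.39 and 2.63 to 4.48. On the chosen probe sets the medians differed between the lists. This argues against carried-over tissue as the whole cause only if it had the make-up of the infarct piece, which was not tested. The other probe sets of Col1a1 and Col3a1 rose less in the remote region than in the infarct, so the gap may depend on the probe set. Carried-over tissue of another make-up, or as a part of the cause, stays open. A single unusual remote array was argued against, since at least 2080 genes were called without any of them, and so were swapped regions, since in 0 pairs with the same title number did the remote array lie farther from sham than the infarct array. A change of the remote tissue itself may contribute, as a hypothesis.

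The third pattern was the lower level of the clock output genes Dbp and Tef in infarcted mice from 4 h to 48 h. A change local to the infarct was argued against as the whole cause, since 4 of 6 changes of Dbp and Tef in remote against sham tissue passed as falls, the largest -2.54 ± 0.33 for Dbp at 48 h. Tef at 4 h passed narrowly (adjusted p = 0.047), and its call ended when any 1 of the 6 arrays was left out, as did that of Tef at 24 h for 2 of the 6. With only the 2 groups in the fit 2 of 6 passed, since the calls of Dbp and Tef at 24 h ended, and 3 of 6 passed with an offset of 0.05 times the median, quantile normalization or no filter, where Tef at 4 h ended. That of Dbp at 48 h held under each alternative run and without each array. A local part stays open: 2 of the 6 changes between infarct and remote passed as falls, both of Tef, by -0.71 ± 0.21 at 24 h (adjusted p = 0.0079) and by -1.26 ± 0.21 at 48 h (adjusted p = 3.1e-06), but this tally moved with single arrays. The Tef call at 24 h ended with only the 2 groups in the fit and without the infarct or the remote array with the middle title number. Dbp passed as a fall at 24 h without the remote array with the middle number (adjusted p = 0.025), and at 48 h, by -1.15, without that with the highest number (adjusted p = 0.0018). The test set beforehand, which asked for 6 or 0 of these, thus cannot tell. Another time of day at harvest stays open: genes of the opposite phase had a median change of 0.54 in the infarct, as such a difference would need. Against it, the output gene Nr1d1 was higher at 4 h, by 0.82 ± 0.21, and the opposite-phase median in remote tissue was -0.17 at 24 h. That median was 0.23 at 4 h and 0.19 at 48 h, which go with it. In remote tissue the opposite-phase gene Arntl was higher at 4 h, by 1.04 ± 0.25 (adjusted p = 0.015), and at 48 h, by 1.00 ± 0.25 (adjusted p = 0.0078). Clock, Cry1 and Nfil3 did not pass there at any of these times. The labels give no time of day, and the sham and infarcted mice of these times carry separate ranges of title numbers. An effect of infarction on the clock stays open as well.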

How the results depend on the processing

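The alternative with the sham lower array alone as control was chosen after the data were seen, and its lone array is assumed to vary like the other groups. Of 739 calls of named genes, 544 held under every alternative apart from left-out arrays. Leaving out single arrays ended the call in 413 of 4434 checks, and 222 of the 739 ended under at least 1 alternative or left-out array. Of the 739 calls, quantile normalization ended 27, no filter 16, the offsets 16 and 17, no replicate block 19, and only the 2 groups compared 135. A fixed block ended 10 of the 225 calls it could check. Of 215 list calls, 54 passed with an estimated correlation, as its construction gives, since correlated genes count for less. Signal over background limits dim genes.

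An offset of 1 times the median gave 7 genes for sham lower against upper, where 0 passed. Remote against sham at 8 weeks, with 8 genes, gave 3 under quantile normalization and 2 with no filter. Sham upper and lower arrays together gave 225 genes for infarct against sham at 1 h (452 otherwise). With only the 2 groups compared, infarct against sham gave 40 at 1 h and 11 at 8 weeks (1407 otherwise). Remote against sham gave 1.4997% of genes (100 genes) at 1 h and 51, 85 and 0 genes at 24 h, 48 h and 8 weeks (8.04% and 299, 588 and 8 genes otherwise), and infarct against remote 8, 1018, 1810 and 0 at 1 h, 24 h, 1 week and 8 weeks (5.10% of genes, 2219, 2745 and 6.46% otherwise). These fits have fewer arrays to estimate the spread, and they use the spread of the 2 groups alone. As run for Dbp and Tef, they also have no replicate block. For infarct against remote, the full model without that block gave 172 genes at 1 h and 195 at 8 weeks. Part of the falls there may thus come from the block and not from the spread. The full model shares 1 estimate over all groups. Where a group varies more than the others, its adjusted p values in the full model can be too small. The infarct arrays at 8 weeks lay far apart for Acadm, at 13084, 9338 and 4784. The 2 zeros are limma counts, where the full model had 545 and 1568 genes at an unadjusted p below 0.05. Against the sham lower array alone, infarct against sham gave 23, 142 and 1630 genes at 1 h, 4 h and 24 h (452, 795 and 2838 otherwise), with 1 control array in place of 3.

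The sign turned for Hba-a1 at 48 h under quantile normalization (0.036), and against the sham lower array alone for Polr2i (0.083) and Pstpip1 (0.299) at 1 h and for Psmd4 (0.011) and Rpl32 (0.077) at 1 week, all in infarct against sham. With beta-actin in place of Gapdh the difference in array quality turned to 0.0687 at 1 h, 0.134 at 4 h and 0.0204 at 8 weeks. Apart from the reasons named, the cause was not tested.

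With no replicate block, remote against sham at 8 weeks gave 2 genes, and infarct against remote 172, 50 and 195 genes at 1 h, 4 h and 8 weeks. With a fixed block infarct against remote at 1 h gave 171. No other count moved by over 1.5 times under either block setting. Infarct and remote arrays with the same number deviated together with a correlation over 0.1 in 7 of 17 pairs (lowest -0.101, highest 0.417). The 3 pairs at 1 week gave 0.219 to 0.417 and those at 48 h 0.0614 to 0.264, while at 1 h, 4 h and 24 h the highest were 0.00359, 0.0375 and 0.0240, so at these early times the pairing rests on the reading of the title numbers. The correlation of 0.148 that the model used at every time was not seen at these times. The counts of infarct against remote at 1 h and 4 h depend in part on it.

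With each array left out, infarct against sham gave 206 to 403, 523 to 595, 2324 to 2733, 2945 to 3243, 3720 to 3865 and 623 to 1761 genes from 1 h to 8 weeks. Remote against sham gave 2.76% to 7.59% of genes at 1 h (8.04% with every array), then 59 to 101, 130 to 408, 287 to 583, 2080 to 2354 and 2 to 8. Infarct against remote gave 53 to 335, 24 to 62, 1492 to 2111, 2625 to 3022, 2128 to 2809 and 7 to 1150. The any-time tests gave 4990 to 5205 and 2479 to 2905, the infarct effect by time 4074 to 4393, the sham time course 715 to 1487, and sham lower against upper 0 to 0 by limma (962 at an unadjusted p below 0.05 with every array). The arrays that moved a count by over 1.5 times are named in the report.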

Other observations

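Some single arrays carried transcripts of other tissues at levels far above their group. Adipoq was also raised over sham on every infarct and remote array at 1 week. Myl7, a myosin light chain gene of the atrium, was at 3157 on the remote array with the middle title number at 1 h, where the median of the 18 sham upper arrays was 40.4 and the highest 530. At 4 h it was raised on all 3 remote arrays, at 267.7, 637.9 and 527.6. The sham upper arrays of that time had 24.1 to 95 and the infarct arrays 22 to 26.4. The 4 h comparisons of remote tissue thus include this difference. Adipoq and Car3, genes of fat cells, were at 2658 and 2124 on the remote array with the lowest number at 4 h, against sham upper medians of 86.4 and 51.6. On the infarct array with the highest number at 8 weeks Adipoq was at 3442, Car3 at 2904 and the erythroid gene Alas2 at 3334. Adipoq and Car3 lay above every sham upper array on other arrays of that time too. They were at 835.5 and 864.5 on the middle infarct array. On the remote arrays with the highest and lowest numbers they were at 655.7 and 616.6, and at 175.5 and 176.5. The lowest infarct and middle remote arrays were not raised, with Adipoq at 74.9 and 79.2. At 1 week Adipoq lay above the highest sham upper value of 114 on all 3 infarct and all 3 remote arrays, between 162 and 1571. The immunoglobulin gene Igkv6-23 was at 12338 on the infarct array with the middle number at 8 weeks, and at 5604 and 3576 on the infarct and remote arrays with the highest number at 1 week, against a sham upper median of 76.6. These genes were chosen after their values were seen.

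Where a gene had more than 1 probe set, the probe sets could differ in direction. At 1 week in infarct against sham, 540 further probe sets were called along with the chosen probe set of their gene. Of these, 50 went the opposite way.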
